A study of Mus musculus with 6 samples.

How the data were processed

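G-quadruplexes, folded structures of guanine-rich DNA, were captured from splenic B cells of C57BL/6J mice with the antibody BG4. Per the labels' protocols, B cells were isolated with a pan B cell kit, fixed with formaldehyde, lysed and sonicated, and the chromatin was treated with RNase A before it was incubated with BG4. Captured DNA was sequenced as paired-end reads of 50 bases. Cells carried a CD19-driven double knockout of Tet2 and Tet3 (DKO) or were of the comparison genotype labelled Dfl. There were 2 BG4 libraries of each genotype and 1 input library of each genotype, 6 in all. The replicate numbers came from the sample titles. Both inputs are numbered 1 there, so replicate 2 has no input of its own in either genotype. Nothing in the labels says that replicates came from separate mice, so p-values measure only the spread between these libraries, which may be technical.

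A single deposited table was used. It gives an RPKM value (reads per kilobase of region, scaled to library depth, to 2 decimals) for each of the 6 libraries in 9722 regions, which the authors named union regions. The submitters' processing notes name the mouse build mm10 (GRCm38) and list Bowtie 1.1.2, SAMtools, Picard 2.7.1, MACS2 and HOMER. They give no role, order or settings for these tools, and how the union regions were made is not given in the sources used here. The regions did not overlap one another. They were 124 to 13890 bp long, with a median of 749 bp, and covered 10.25 Mb. Of them, 9591 lay on the 19 autosomes, 98 on X, 9 on Y, 8 on the mitochondrial genome and 16 on unplaced contigs. Values that were compared between libraries were the authors' RPKM, so a library in which more reads fell in the regions has higher values everywhere, and no further scaling was applied in the main comparison.

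Depth was read from the low values. For regions under 400 bp and values under 4 RPKM, the length of a region (end minus start plus 1) and 1 depth per library turned 99.6% to 100.0% of values into whole reads within the rounding of the table, against 4.8% to 7.1% by chance. The implied depths were 17.4 and 16.9 M reads (M, megareads) for the Dfl BG4 libraries, 20.3 and 22.4 M reads for the DKO BG4 libraries, and 25.3 (Dfl) and 23.0 M reads (DKO) for the inputs. These depths hold only up to a whole-number factor. The median region then held 16 and 21 reads in the Dfl BG4 libraries, 28 and 37 in the DKO BG4 libraries, and 11 and 9 in the inputs, so single regions were shallowly covered. Reads recovered in this way were compared between libraries by a chi-square per region around 1 scale factor. The value was 1.16 for the Dfl pair and 1.08 for the DKO pair, above sampling noise in both, so no library was treated as a copy of another. Between genotypes it was 1.12 for Dfl replicate 2 against each DKO library and 1.19 and 1.41 for Dfl replicate 1, so Dfl replicate 1 stood apart from the other 3.

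BG4 signal was compared between DKO and Dfl with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided) on log2(RPKM + 1) of the 4 BG4 libraries, with genotype as the term in the model. The Benjamini-Hochberg adjusted p threshold was 0.05, with no filter and no fold threshold. A fold change on this scale understates the change of low values. BG4 was compared with input by limma over all 6 libraries with genotype as a covariate. Sets of regions were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.

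Regions were placed against the gene spans of a RefSeq table of GRCm38.p6, which holds 49997 genes, 34631 of them protein-coding or long non-coding. This table has no strand, exons or sequence. Promoters could therefore not be told from gene 3' ends, and the planned promoter class became regions within 1 kb of either end of such a gene (gene ends). The remaining classes were gene interior and intergenic. A region was given to a gene list when it overlapped the span of a listed gene or the 5 kb on either side, where the plan had the upstream side alone, with an overlap of at least 1 bp. Regions are called by the overlapping or nearest such gene, which 9706 regions have. Exons, introns and UTRs were not separated. The planned classes by G-quadruplex motif, GC fraction and CpG content need a genome sequence and were not run.

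The 14 gene lists and the rule for named regions were fixed before the data were examined. The rule took the 12 regions with the largest log2 fold change in each direction among those past the threshold, with both DKO values on one side of both Dfl values and a mean signal at or above the median region. Where fewer passed in a direction, it filled to 6 with the smallest unadjusted p. It also took each region at Tet2, Tet3, Myc and the immunoglobulin constant genes, up to 4 regions per gene list by unadjusted p, and the 3 regions of highest BG4 signal.

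The fit was tested on simulated reads for the 9722 regions at the depths of the 4 BG4 libraries, with 200 changed regions. With no library-wide shift it recovered 2.0% of 2-fold and 41.0% of 4-fold changes and called 0 unchanged regions. With library-wide shifts as large as those between the real libraries it recovered 25.0% and 67.0% and also called 51 unchanged regions, 48 of them as higher in DKO. After centring of the shifted libraries it recovered 2.0% and 60.0% and called 4 unchanged regions. The simulated reads had 1 dispersion, 0.003, in all regions, so they lack any difference in spread between regions. The real libraries gave 0 calls after centring, so these recovery rates may not hold for them. Settings varied, as fixed in advance, were other pseudocounts, a filter on low signal, quantile normalization, median centring, BG4 over input (1 input library per genotype, so its noise is not in the p values and calls made this way are not reported for single regions), the replicate number as a block, another fit, other thresholds, leaving out X and Y and leaving out each library. Chosen after the data were seen were voom on the recovered reads and leaving out 2 kinds of region.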

Results

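BG4 capture was measured in B cells from mouse spleen that lacked Tet2 and Tet3, the enzymes that oxidise 5-methylcytosine, and in B cells labelled Dfl. BG4 is an antibody that binds G-quadruplexes, and the comparison asks whether loss of TET enzymes changes the level of these structures along the genome. There were 2 BG4 libraries per genotype, with implied depths of 16.9 to 22.4 M reads (M, megareads), and 1 input library per genotype, of 25.3 (Dfl) and 23.0 M reads (DKO). The values were the authors' RPKM over 9722 union regions of mm10. Of these regions, 6499 (66.8%) lay within 1 kb of a gene end, 1971 (20.3%) in gene interiors and 1236 (12.7%) between genes.

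The regions were enriched in BG4 libraries over input in both genotypes. BG4 signal was higher than input in 8667 regions and lower in 11 (limma, adjusted p under 0.05), as is built in where regions are chosen for BG4 signal. The share of a library's reads that fell in the regions was 0.591% in the Dfl input and 0.547% in the DKO input. It was 1.39% ± 0.26 (SD, n = 2) in Dfl BG4 libraries and 1.90% ± 0.22 (SD, n = 2) in DKO BG4 libraries. The highest signals of all were at regions that were also high in input. A region of chromosome 2 (57629533 to 57629714), 258814 bp from Gpd2, held 102.16 ± 9.07 RPKM in Dfl and 118.64 ± 8.02 in DKO (SD, n = 2) against inputs of 95.25 and 81.59. A region inside the non-coding gene 2700054A10Rik (chromosome 17, 13552838 to 13553077) held 97.29 ± 26.93 and 112.17 ± 24.73 RPKM, with inputs of 76.34 and 75.8. A region in mitochondrial CYTB, the cytochrome b gene, held 75.69 ± 3.19 and 81.52 ± 11.79 RPKM, with inputs of 39.22 and 47.62. The differences between genotypes at these 3 regions did not pass the threshold (limma, adjusted p = 0.138, 0.214 and 0.549) in the main comparison. At the Gpd2 and 2700054A10Rik regions they passed with pseudocount 5 (log2 fold change 0.207 and 0.205) and without DKO replicate 1 (0.283 and 0.438), but both turned after centring (-0.074 and -0.076), and 2700054A10Rik also without Dfl replicate 1 (-0.069) and without DKO replicate 2 (-0.011).

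**Figure D1:**
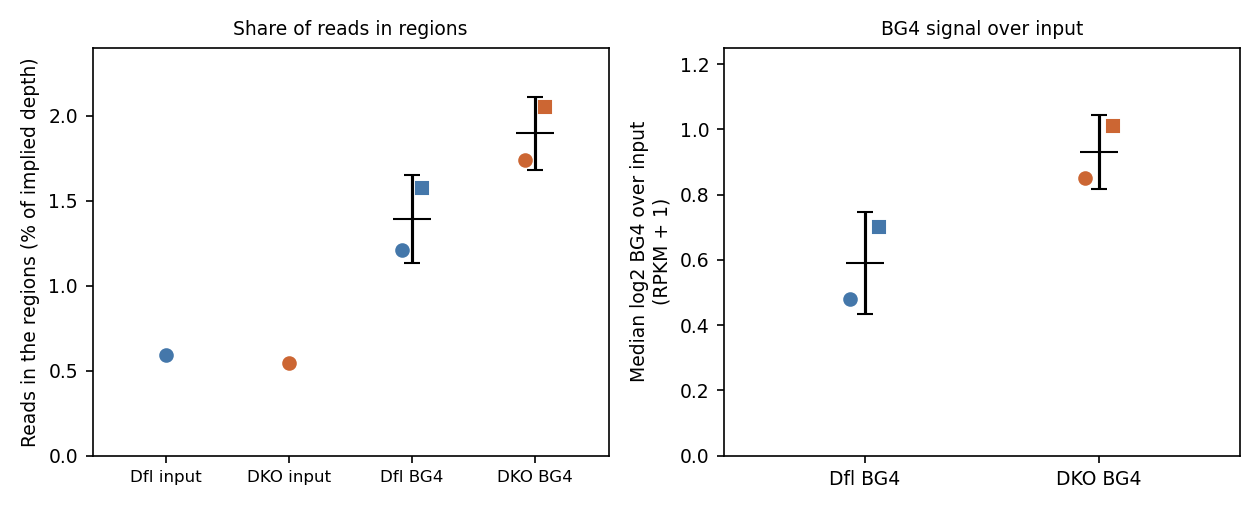
Left, reads in the 9722 regions as a percentage of each library's implied depth. Right, median over regions of log2 BG4 over the input of the same genotype, on RPKM + 1. Circles are replicate 1 and squares replicate 2, with horizontal bars and error bars for the mean and SD of 2 libraries; each input is 1 library. DKO BG4 libraries, at 1.742% and 2.049%, lie above Dfl BG4 libraries, at 1.208% and 1.577%, and the inputs lie at 0.591% (Dfl) and 0.547% (DKO).

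BG4 signal was higher in DKO than in Dfl B cells across most regions. The log2 fold change was above 0 in 8851 of the 9722 regions (91.0%), with a median of 0.28, or 1.21-fold on the RPKM + 1 scale. Both DKO libraries lay above both Dfl libraries in 5260 regions (54.1%) and below them in 175 (1.8%), where chance gives a single region 16.7% in each direction. All regions share the library-wide differences and are not independent, so these percentages do not test the genotypes. Over the input of the same genotype, the median log2 signal was 0.59 ± 0.16 in Dfl and 0.93 ± 0.11 in DKO (SD, n = 2), while the median difference between the DKO and the Dfl input was -0.05. The share of reads in regions was 1.36 times as high in DKO as in Dfl libraries, with an exact two-sided permutation p of 0.33, the smallest that 2 against 2 libraries allow. Libraries of one genotype also differed. The median difference was 0.22 between the Dfl libraries and 0.14 between the DKO libraries, and DKO minus Dfl medians ran from 0.09 to 0.47 over the 4 pairs of libraries. Over regions, the Dfl libraries correlated at 0.61 with each other (Spearman). Each correlated more with the DKO libraries, Dfl replicate 1 at 0.64 and 0.66 and Dfl replicate 2 at 0.73 and 0.77. The DKO libraries held more reads in the median region (28 and 37, against 16 and 21 in Dfl). Counting noise lowers correlations of shallow libraries, so these values do not place Dfl replicate 2 with DKO.

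**Figure D2:**
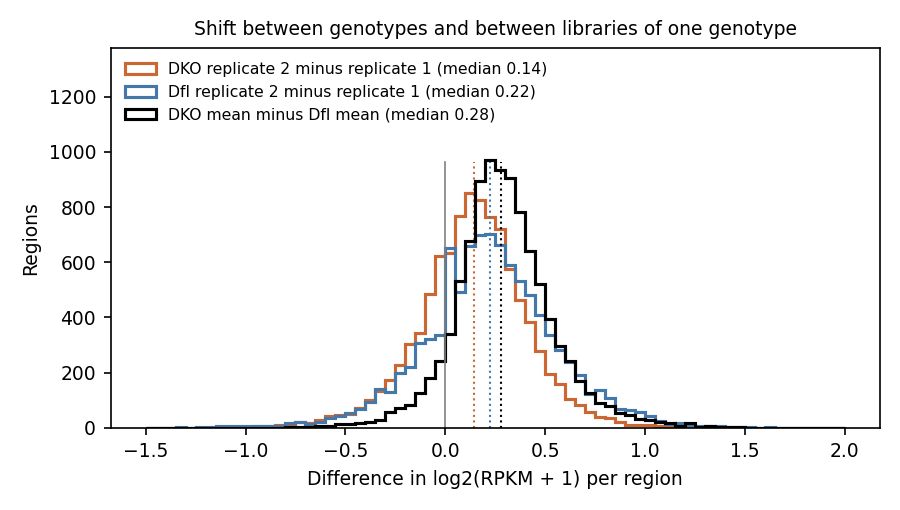
Histograms over the 9722 regions of the difference in log2(RPKM + 1), in bins of 0.05, for the mean of the DKO minus the mean of the Dfl BG4 libraries (black) and between the 2 libraries of each genotype (orange, DKO; blue, Dfl). Dotted lines mark medians of 0.28, 0.14 and 0.22; the black curve compares means of 2 libraries, so it is narrower than a difference of single libraries.

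Tet2 and Tet3, the deleted genes, each had 1 region, and neither passed the threshold. The Tet2 region (chromosome 3, 133544276 to 133544673, at an end of the gene) held 1.88 and 3.28 RPKM in the Dfl libraries and 3.83 and 3.93 in the DKO libraries, a log2 fold change of 0.47 (SE 0.33, limma adjusted p = 0.404). The Tet3 region (chromosome 6, 83455090 to 83457359, at an end of the gene) held 0.86 and 1.51 RPKM in Dfl and 1.32 and 2.09 in DKO, a log2 fold change of 0.31 (SE 0.23, limma adjusted p = 0.424). The part of each gene that was deleted is not given in the sources used here, so these regions check nothing about the knockout. At the immunoglobulin heavy chain locus, 1 region (chromosome 12, 113424286 to 113425299) lay between Ighm and Ighj4, 1556 bp from Ighm, in the interval that holds the mu switch sequence. It held 4.04 ± 1.22 RPKM in Dfl and 6.52 ± 1.88 in DKO (SD, n = 2), a log2 fold change of 0.57 (SE 0.37, limma adjusted p = 0.38). Without each library in turn, the log2 fold change ran from 0.189 to 0.761 at the Tet2 region, from 0.093 to 0.526 at the Tet3 region and from 0.317 to 0.832 at the Ighm region, and it passed the threshold at none of them. The table held no region within 5 kb of the other listed constant genes or of Myc, whose nearest region was 191.0 kb away.

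Single regions that passed the threshold were nearly all higher in DKO: 124 were higher and 4 lower. The highest fold change was at an end of Pawr, a pro-apoptotic regulator (chromosome 10, 108331964 to 108332203). Signal there was 0.36 ± 0.18 RPKM in Dfl and 4.37 ± 0.67 in DKO (SD, n = 2), a log2 fold change of 1.98 (SE 0.25, limma adjusted p = 1.4e-09), on 1 and 2 reads in Dfl and 19 and 26 in DKO. At an end of Pgbd5, a gene derived from a piggyBac transposase (chromosome 8, 124434456 to 124434792), signal was 1.04 ± 0.27 RPKM in Dfl and 5.18 ± 1.13 in DKO, a log2 fold change of 1.59 (SE 0.30, limma adjusted p = 4.9e-04). Gene-end regions also rose at Gng7, a G protein subunit gene (log2 fold change 1.49), Dixdc1, a Wnt pathway gene (1.42), Slc25a11, a mitochondrial carrier gene (1.40), Smad5, a transducer of BMP signals (1.36), and Dmxl2 (1.32). Regions in gene interiors rose at Rcsd1 (1.49), Lrrc74b (1.38), Atxn1 (1.37) and Ralgps2, which encodes an activator of Ral GTPases (1.37). A region 2716 bp from Sgca, a muscle sarcoglycan gene, rose by 1.32. Only 1 of these 12 regions lay outside the first of the 3 unlabelled stretches of rows. That stretch held 888 regions with a median length of 240 bp and a median log2 change of 0.56, and how it was chosen is not given. Less the median change of all regions, these 12 fold changes were 1.69 at Pawr, 1.31 at Pgbd5 and 1.04 to 1.21 at the others. With voom on the recovered reads 4 of the 12 calls held, with pseudocount 0.1 it was 8, and with pseudocount 5 all 12. Of the 12 calls, 5 held without Dfl replicate 1, 12 without Dfl replicate 2, 4 without DKO replicate 1 and 1, that at Pawr, without DKO replicate 2. The calls lost without a DKO library kept log2 fold changes within 1.5 times those of the main fit, 1.258 to 1.491 at the 8 lost without DKO replicate 1 and 1.181 to 1.781 at the 11 lost without DKO replicate 2. Of the 7 lost without Dfl replicate 1, 5 also stayed within 1.5 times, while the log2 fold change fell to 0.65 at Lrrc74b (limma adjusted p = 0.428) and 0.75 at Slc25a11 (0.302).

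The 4 regions called lower in DKO had signal under the median region, and they are named after their values were seen. They lay inside Arpp19, which encodes a regulator of mitotic phosphatase (log2 fold change -1.38, limma adjusted p = 1.7e-06), inside Ptprn (-0.76), inside Rpap2 (-0.77) and 2513 bp from Tulp3 (-0.72). The Arpp19 region (chromosome 9, 75050153 to 75050291) rested on 7 and 3 reads in Dfl and 0 and 1 in DKO, and the Dfl input there, at 1.7 RPKM, also exceeded the DKO input, at 0.62. Over these inputs, 1 library each, its log2 fold change was -0.64, and its call was lost without DKO replicate 1, with a log2 fold change of -1.176 (adjusted p = 0.0614). The Tulp3 call was lost without each of the 4 libraries in turn (log2 fold change -1.016 to -0.423). The Ptprn call was lost without Dfl replicate 2 (-0.49) and without DKO replicates 1 and 2 (-0.666 and -0.847), and the Rpap2 call without Dfl replicate 1 (-0.594) and without DKO replicates 1 and 2 (-0.408 and -1.132). With voom on the recovered reads none of the 4 passed, although the log2 fold changes were larger on that scale (-2.886 at Arpp19, -1.276 at Ptprn, -1.346 at Rpap2 and -1.652 at Tulp3). Of regions at or above the median signal, none passed in this direction in the main comparison. The 6 with the smallest unadjusted p were at G730013B05Rik (log2 fold change -0.99, limma adjusted p = 0.0592), Arhgap22 (-0.74), Sema3b (-0.70), Capn15 (-0.66), A430010J10Rik (-0.54) and Larp4b (-0.51). G730013B05Rik and Arhgap22 passed without Dfl replicate 2 (-0.971 and -0.930), while Arhgap22 turned over input (0.150).

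**Figure D3:**
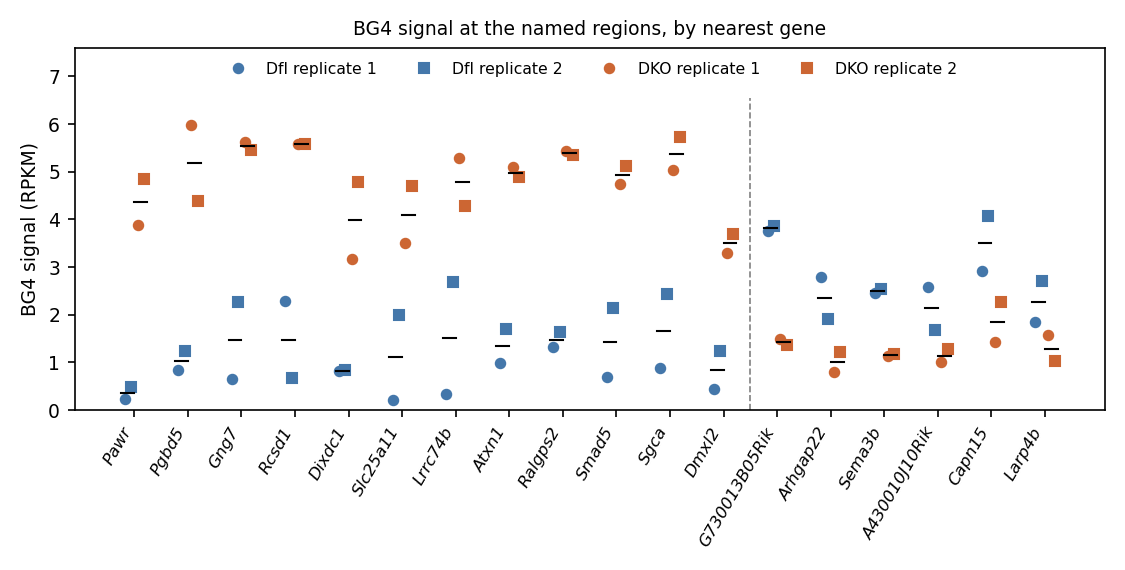
BG4 signal in RPKM at each region named by the fixed rule, labelled by its overlapping or nearest gene. Circles are replicate 1, squares replicate 2, blue Dfl, orange DKO, and short bars the means of 2 libraries. Left of the dashed line are the 12 regions called higher in DKO, from 0.36 to 4.37 RPKM at Pawr; right of it are 6 with lower DKO values that missed the threshold, such as G730013B05Rik at 3.81 and 1.43 RPKM.

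The 124 regions called higher had log2 fold changes of 0.52 to 1.98, a median length of 268.5 bp and medians of 4 and 6 reads in the Dfl libraries against 17.5 and 20 in the DKO libraries. Their number depended on the scaling of the libraries. After median centring or quantile normalization of the libraries, limma called 0 regions in either direction, and at an unadjusted p under 0.05 the split was 382 higher and 339 lower (centring) or 305 higher and 300 lower (quantile), against 1586 and 52 without scaling. At the 124 regions the median log2 fold change was 1.054 (median SE 0.26) before centring and 0.764 (median SE 0.20) after it. The moderated degrees of freedom of the fit fell from 170.6 to 7.1 with centring and 6.7 with quantile normalization, of which 2 are residual in each. With the 170.6 of the main fit, the centred values would give 130 higher and 110 lower calls. Those degrees of freedom were estimated from the unscaled values, so these counts are not valid calls. The fall to 0 calls therefore went with the lower degrees of freedom, not with the folds and SE alone. Whether the 124 regions differ beyond the shift stays open, while the excess of higher calls went with the shift. The adjusted p values of the main fit also rest on the 170.6. Voom on the recovered reads called 7 higher and 0 lower, with 1776 and 10 at that unadjusted p. Counts of higher and lower calls were 54 and 4 without Dfl replicate 1, 774 and 9 without Dfl replicate 2, 17 and 0 without DKO replicate 1, and 4 and 1 without DKO replicate 2. The call at Pawr held without each library in turn, but had an adjusted p of 0.064 after centring (log2 fold change 1.69, SE 0.14) and 0.186 after quantile normalization (1.69, SE 0.16).

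Regions at gene ends had a median log2 fold change of 0.29, those in gene interiors 0.25 and those between genes 0.23. In the main comparison none of these classes differed from the remaining regions past the threshold (camera, adjusted p = 0.0772 for gene ends, 0.251 for interiors and 0.0772 for intergenic regions, and 0.787 for each with an estimated correlation). This turned on single libraries. The difference of gene ends from other regions, 0.059 in the main fit, was 0.002 without Dfl replicate 1 and 0.117 without Dfl replicate 2 (camera adjusted p = 2.2e-04), and that of intergenic regions, -0.062, was 0.001 and -0.125 (adjusted p = 1.7e-04 for the latter). Both also passed without DKO replicate 1, after centring, with replicate as a block and with voom. In groups of 20% of regions by signal, from the weakest upward, medians at gene ends were 0.19, 0.25, 0.29 and 0.34. Those in interiors were 0.16, 0.23, 0.30 and 0.33, and those between genes 0.17, 0.20, 0.26 and 0.31. In the 20% with the strongest signal gene ends were lowest, with medians of 0.42 at gene ends, 0.48 in interiors and 0.48 between genes. Differences within these groups were not tested. Of the 124 regions called higher, 54 lay at gene ends, 38 in interiors and 32 between genes.

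B cell identity genes, such as those for surface receptors and lineage transcription factors, had 35 regions at 19 genes, of which 2 rose in DKO and 0 fell over all regions tested, and 4 rose adjusted over the list alone. A region within 5 kb of Pou2f2, which encodes the transcription factor Oct-2 (chromosome 7, 25082521 to 25082858, in the span of Zfp574), rose from 0.69 ± 0.01 to 2.15 ± 0.04 RPKM (SD, n = 2), a log2 fold change of 0.90 (SE 0.22, limma adjusted p = 0.0124). A second region (chromosome 11, 106308216 to 106308591) lay 2750 bp from Cd79b, which encodes a signalling chain of the B cell receptor. It rose from 1.00 ± 0.97 to 2.74 ± 0.16 RPKM, a log2 fold change of 0.99 (SE 0.25, limma adjusted p = 0.0182). Pou2f2 and Cd79b each also had a region at the gene itself (0.0 kb away), and these regions did not pass. Regions at Ebf1 and Pax5, regulators of the B lineage, had log2 fold changes of 0.67 and 0.65 (limma adjusted p = 0.0955 and 0.121). These ran from 0.394 to 0.946 and from 0.297 to 1.007 without each library in turn. The Pax5 region passed without Dfl replicate 2 (adjusted p = 0.014). The Pou2f2 call was lost without Dfl replicate 1 (adjusted p = 0.0867) and without either DKO library, while its log2 fold change stayed between 0.885 and 0.912 without each library in turn. The Cd79b call was lost without either DKO library and without Dfl replicate 2 (adjusted p = 0.216), and its log2 fold change ran from 0.473 without Dfl replicate 2 to 1.500 without Dfl replicate 1. The Pou2f2 and Cd79b calls were also lost with pseudocount 0.1 (limma adjusted p = 0.0527 and 0.0785) and with voom on the recovered reads (0.18 and 0.134). On these scales their log2 fold changes were larger (1.510 and 1.708, and 1.515 and 1.736). The list as a whole had a median of 0.30 and did not stand apart from other regions (camera, adjusted p = 0.384, and 0.992 with an estimated correlation).

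Genes mutated off target by AID or translocated in lymphoma had 31 regions at 22 genes. Of these 1 rose, the Cd79b region, and 3 rose adjusted over the list alone, those near Cd79b and at Ebf1 and Pax5. All 3 are shared with the previous list. Germinal centre and plasma cell genes had 11 regions at 8 genes, of which 0 passed, and the values with the smallest unadjusted p were 0.50 and 0.55 at Mef2b and 0.53 at Prdm1, a regulator of plasma cells. Regions of genes for B cell receptor, CD40 and NF-kB signalling numbered 28 at 21 genes. None passed over all regions and 2 rose adjusted over the list alone. They lay within 5 kb of Bcl10, at an end of 2410004B18Rik (log2 fold change 1.21, limma adjusted p = 0.0576), and in Pik3cd (0.90, limma adjusted p = 0.0772). Genes of MHC and antigen presentation had 21 regions at 14 genes, with 0 calls over all regions and 1 adjusted over the list alone, within 5 kb of H2-D1 (log2 fold change 0.85, limma adjusted p = 0.0576). Without Dfl replicate 2, the regions near Bcl10 (log2 fold change 1.569) and in Pik3cd (1.148) passed. The camera test gave adjusted p = 0.693 for the AID list, 0.672 for germinal centre and plasma cell genes, 0.976 for signalling genes and 0.693 for antigen presentation.

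Genes that act on G-quadruplexes and R-loops had 23 regions at 17 genes, with a median log2 fold change of 0.34 and 0 calls, also when adjusted over the list alone. Their smallest unadjusted p values were at Thoc5, of the THO complex (log2 fold change 0.64, limma adjusted p = 0.0886), Ddx11 (0.66) and Top3b (0.69). Their values ran from 0.585 to 0.696, from 0.172 to 1.141 and from 0.222 to 1.167 when each library was left out in turn. The Ddx11 and Top3b regions passed without Dfl replicate 2 (adjusted p = 0.0147 and 0.0155). Genes of DNA methylation and demethylation had 17 regions at 15 genes, with 0 calls over all regions and 2 adjusted over the list alone, at Idh2 (log2 fold change 0.97, limma adjusted p = 0.104) and Mecp2, which encodes a methyl-CpG binding protein (0.73, limma adjusted p = 0.113). Dnmt3a had a value of 0.77. The DNA damage response had 19 regions at 17 genes, a median of 0.22 and 0 calls, with values of 0.78 at Rnf8, 0.44 at Brca1 and 0.36 at Atm. Without Dfl replicate 2, the regions at Idh2 (log2 fold change 1.151) and Mecp2 (0.881) passed. The camera test gave adjusted p = 0.888, 0.877 and 0.672 for these 3 lists.

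Ribosomal protein genes had 80 regions at 66 genes, with a median log2 fold change of 0.28. Of these 1 rose, within 5 kb of Rpl23a and in the span of Tlcd1 (0.87, SE 0.24, limma adjusted p = 0.0352), and 2 rose adjusted over the list alone. The Rpl23a call was lost without Dfl replicate 1 (log2 fold change 0.545, adjusted p = 0.45) and without either DKO library (0.881 and 0.851). Replication-dependent histone genes had 14 regions over 33 genes, a median of 0.14 and 0 calls, with 0.54 at H3c6 and 0.44 at H2bc7. The H3c6 region passed without Dfl replicate 2 (0.941), and ran from 0.136 to 0.941 without each library in turn. Their lower median had an unadjusted camera p of 0.0384 and an adjusted p of 0.384. The camera test gave adjusted p = 0.888 for ribosomal protein genes and for the single region of the immunoglobulin constant genes.

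Markers of other spleen cells gave few regions. T cell markers had 7 regions at 5 genes, 0 calls over all regions and 1 adjusted over the list alone, at Cd5, which is also expressed on a subset of B cells (log2 fold change 1.01, limma adjusted p = 0.0512). That region passed without Dfl replicate 2 (1.074). Myeloid markers had 8 regions at 5 genes and erythroid markers 4 regions at 3 genes, with 0 calls in each and medians of 0.27 and 0.20. The camera test gave adjusted p = 0.888 for each of the 3 lists, and 0.992 for each of the 14 lists with an estimated correlation. The camera direction was down for T cell markers and for signalling genes although the mean of each lay 0.01 above that of other regions; the T cell median was 0.11.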

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

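The tests of voom on recovered reads, of leaving out regions of high input, of leaving out the first stretch of rows, of the degrees of freedom and of redrawn inputs were chosen after the data were seen; the others were planned. The direction of the shift held with each pseudocount, with the filter, over input and without any library, while the number of called regions moved with most settings. The main counts were 124 higher and 4 lower. They were 16 and 1 with pseudocount 0.1, 147 and 8 with pseudocount 5, 144 and 1 for regions with mean RPKM of 2 or more, 1540 and 92 for BG4 over input, 108 and 2 with no trend, 857 and 17 at an unadjusted p with a log2 change of 0.6, 277 and 10 at an adjusted p under 0.1, 7 and 0 with voom and 70 and 4 without the first stretch of rows. They were 113 and 4 with 6 libraries in the fit, 118 and 4 without X and Y and 130 and 4 without regions of high input. Similar counts did not always hold the same regions. Of the higher calls, 68 of 144 with the filter and 63 of 108 with no trend were also called in the main fit. With pseudocount 5 it was 114 of 147, and with 6 libraries 102 of 113. The counts over input carry no evidence for single regions: each genotype has 1 input, whose counting noise enters the fold but not the spread. With both inputs redrawn from 1 pooled rate, so that they differed by counting noise alone, the fit still called a median of 1027 higher and 74.5 lower over 20 draws. Quantile normalization and median centring gave 0 and 0 (limma; 305 and 300, and 382 and 339, at an unadjusted p under 0.05). With the moderated degrees of freedom of the main fit, 170.6 in place of 6.7 and 7.1, the same values would give 82 and 86, and 130 and 110. These counts borrow degrees of freedom estimated from the unscaled values and are not valid calls. Without each library in turn, counts ran from 4 to 774 higher and 0 to 9 lower; the lone library of a genotype was then assumed to vary like the pair of the other.

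With the replicate number as a block, limma called 0 higher and 0 lower, with 2366 and 47 at an unadjusted p under 0.05; this fit leaves 1 residual degree of freedom. The deviations of same-numbered libraries from their genotype means correlated at 0.07 over regions, a measure that leaves out a shift common to all regions. Replicate 2 lay above replicate 1 in both genotypes (median log2 difference 0.22 in Dfl and 0.14 in DKO). Whether the numbers pair the libraries therefore stays open. Under the block the classes differed from other regions by 0.059 (gene ends), -0.039 (interiors) and -0.062 (intergenic). Each passed the threshold in camera at the preset correlation. The main comparison had the same differences, and there none passed. An estimated correlation was used in the main comparison alone, where camera gave adjusted p = 0.787 for each class, so it does not test the calls under the block. The correlations estimated there (0.41, 0.15 and 0.06 for gene ends, interiors and intergenic regions) exceeded the preset of 0.01. The calls under the block rest on that preset and therefore do not establish a class difference.

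The median log2 change of 0.28 became 0.447 with pseudocount 0.1, 0.107 with pseudocount 5, 0.468 with voom, -0.005 after quantile normalization and -0.009 after centring. Median log2 signal over input (0.59 Dfl, 0.93 DKO) became 1.149 and 1.731 with pseudocount 0.1, 0.190 and 0.316 with pseudocount 5, and 0.933 and 1.429 for regions with mean RPKM of 2 or more, where 2786 regions exceeded input because fewer were tested. The ratio of shares of reads in regions, 1.36, ran from 1.202 to 1.570 without each library in turn.

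Class differences passed the threshold after centring (0.059 gene ends, -0.062 intergenic) and with voom (0.084, -0.049 and -0.095 for gene ends, interiors and intergenic regions). They turned for regions with mean RPKM of 2 or more (-0.044, 0.055 and 0.023). They ran from 0.002 to 0.117, -0.074 to -0.003 and -0.125 to 0.001 without each library in turn. They passed without Dfl replicate 2 (camera adjusted p = 2.2e-04, 0.0212 and 1.7e-04) and, for gene ends and intergenic regions, without DKO replicate 1 (0.0227 and 0.02). Dfl replicate 1 decided the direction between genes (0.001 without it). With an estimated correlation no class passed in the main comparison (adjusted p = 0.787).

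No gene list passed camera's threshold in any setting run, and differences near 0 changed sign. The signalling list turned with pseudocount 0.1 (-0.010), over input (-0.041), with voom (-0.005), without the first stretch (-0.026) and within 1 kb of gene ends (-0.026). T cell markers turned with pseudocount 0.1 (-0.029), with voom (-0.039) and without the first stretch (-0.120). The AID list turned with the filter (-0.029) and within 1 kb of gene ends (-0.004), the germinal centre list within 1 kb of gene ends (-0.029), myeloid markers over input (0.036) and within 1 kb of gene ends (0.028), and erythroid markers with the filter (0.092) and over input (0.006). Without each library in turn the ranges were -0.045 to 0.059 for signalling, -0.059 to 0.073 for T cell, -0.023 to 0.115 for AID, -0.001 to 0.134 for germinal centre, -0.075 to 0.031 for myeloid, -0.112 to 0.005 for erythroid, -0.181 to 0.021 for antigen presentation and -0.043 to 0.030 for ribosomal protein genes.

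Of 59 regions followed through the settings, none of the 19 called ones changed direction; 8 and 16 calls held without Dfl replicates 1 and 2, 4 and 2 without DKO replicates 1 and 2, and 4 with voom. Of the 40 not called, 16 gained a call over input, where noise of the inputs is not in the p value, 12 without Dfl replicate 2, 7 with pseudocount 5, 5 with the filter (21 followed), 2 without DKO replicate 1, and 1 each without regions of high input and without the first stretch. The 3 regions of highest signal turned after centring (Gpd2 -0.074, 2700054A10Rik -0.076, CYTB -0.190), CYTB also after quantile normalization (-0.141) and over input (-0.175), and Arhgap22 turned over input (0.150). Without each library in turn, 2700054A10Rik ran from -0.069 to 0.497 and CYTB from -0.047 to 0.245. For these turns, and for the settings above where no reason is given, the cause was not tested. At these depths, with 2 libraries per genotype and 1 dispersion for all regions, 2.0% of simulated 2-fold changes were recovered without library-wide shifts. With such shifts 25.0% were recovered, beside 51 false calls. Depth was not varied on its own. Classes by G-quadruplex motif and base composition were not run.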

Other observations

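All tests of the first pattern below, the tests of the pseudocount, of Y DNA, of chromosomes and of gene ends among called regions were chosen after the result was seen; the tests of diluted signal, of low counts on Y and of the end of X were set before their results were seen. For the last 2, the rules that decide the label were changed after the values were seen: 2 Y regions now suffice if the change of each is at least 2 times that of all regions, where 3 regions were asked for, and the interval for X must now exclude the change of all regions. The comparison of X with regions of like signal was also chosen after.

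Some regions carried strong signal in input and BG4 alike. The 12 regions beyond the last gene of a nuclear chromosome in the gene table held 45.1 to 70.3 RPKM in BG4 libraries and 36.0 to 52.4 RPKM in inputs, and their summed BG4 signal was 1.17 (Dfl) and 1.30 (DKO) times input, against 2.36 and 3.47 for all regions. Their median log2 change was 0.09, with 0 calls. The 8 mitochondrial regions had a median log2 change of 0.11, and the summed signal there was 1.79 (Dfl) and 1.43 (DKO) times input. The table's rows run in 3 unlabelled stretches. The first, of 888 regions with a median length of 240 bp, held 53 of the 124 regions called higher and had a median log2 change of 0.56, against 0.23 and 0.32 in the second and the third.

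Regions called higher lay at gene ends in 43.5% of cases, against 66.8% of all regions (odds ratio 0.38, Fisher's exact p = 1.2e-07, two-sided, regions not being independent). Among regions under 400 bp the shares were 40.8% and 46.7% (odds ratio 0.78, Fisher's exact p = 0.228), so part of the difference went with length.

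The first pattern is the higher BG4 signal in DKO across most regions. A single scale factor on a whole library would move regions of strong input as much as others, but the 87 regions with input above 5 RPKM had a median log2 change of 0.22 (bootstrap 95% interval 0.16 to 0.26) with pseudocount 0.1, against 0.45 for the others. More DNA of the regions in the DKO sample is argued against for replicate 1 alone, whose inputs had a DKO over Dfl ratio of reads in regions of 0.92. Replicate 2 has no input, so this explanation stays open there. Capture efficiency that differed between libraries may account for the shift: after subtraction of input, libraries of one genotype differed by 0.51 on average (log2), against 0.76 between genotypes, and the ratio was 1.62 between the Dfl libraries and 1.26 between the DKO libraries, against 1.69 between genotypes. The values between genotypes compare means of 2 libraries, which vary less than the single libraries compared within a genotype. The spread within a genotype therefore looks larger beside them than it is. An effect of Tet2 and Tet3 loss stays open beside capture efficiency, since 2 libraries per genotype do not separate the explanations, and so does the choice of the regions, whose making is not given in the sources used here.

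The second pattern is a shift that grew with signal, from a median of 0.18 in the 20% of regions with the weakest signal to 0.44 in the 20% with the strongest, without regions of high input. The pseudocount alone would not leave a trend at 0.1, where the strongest regions still exceeded the weakest by 0.25. Background reads that dilute the fold at low signal may account for it, since after subtraction of input the DKO over Dfl ratio was 1.70 in the weakest and 1.73 in the strongest regions, 1.02 times as large. The same subtraction gave 1.53 and 1.68 between the Dfl libraries. A hypothesis is therefore that the fold was about the same at weak and strong regions; a biological difference between such regions was not tested.

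The third pattern is at chromosome Y, where all 9 regions had both DKO libraries above both Dfl libraries, with a median log2 change of 0.83. Of them, 7 lay between 90742082 and 90784568 at the distal end, in or near the pseudoautosomal sequence that Y shares with X. As a set, the 9 Y regions exceeded other regions in a camera test over 23 chromosomes and contigs (adjusted p = 0.00393). After median centring of the libraries the camera adjusted p was 2.8e-05 for Y, and the contig Un_JH584304 passed as well (0.0337). With an estimated correlation the camera adjusted p was 0.998 for each of the 23, and the unadjusted p for Y was 0.126. Alone, 2 Y regions passed (limma adjusted p = 0.0447 and 0.0488), the first on 3 reads in Dfl replicate 1. More Y DNA in DKO is argued against for replicate 1 alone, whose inputs had a ratio of 0.88. It stays open for replicate 2, which has no input. Low counts alone are argued against by the 2 Y regions with 20 or more reads in every BG4 library, whose log2 changes of 1.31 (SE 0.38, adjusted p = 0.0488) and 1.10 (SE 0.37, adjusted p = 0.106, so past the threshold in the former alone) had a median of 1.21. Reads shared with the end of X stay open: the 8 most distal X regions, 5 of them at Mid1, had a median of 0.59, which met the prediction written beforehand, but its bootstrap interval of 0.13 to 0.69 includes the 0.28 of all regions, and the 6 without strong input had a median of 0.61 (interval 0.51 to 0.72) against 0.49 (0.47 to 0.51) in 721 other regions of like signal; an effect of genotype also stays open, untested.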
